A study of Mus musculus with 6 samples.

How the data were processed

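Tumour DNA labelled with Cy5 and DNA of surrounding liver labelled with Cy3 were hybridised on 6 Agilent mouse arrays, 2 tumours from each of 3 mice, per the labels. No dye swap was made, so a constant dye effect cannot be removed. The deposited scanner files were made with Agilent Feature Extraction, version 10.2.1.3 for the M1 arrays and 9.5.1.1 for the others, per the file headers. The processed signals in these files are intensity values from which the background had been subtracted by spatial detrending and which had been normalised linearly between dyes, per the file headers. The mean and local background signals are intensity values of the scanner, per the file headers. The deposited LogRatio is the log10 of processed Cy5 over processed Cy3, per the file headers. The deposited series table held this log10 ratio without change (largest difference 0), with column medians of 0.000174, 0.0032, -0.0039, 0.0037, 0.0034 and -0.00071 in the order of the labels, so that its scale and direction are those of the arrays and it was not centred further. The outlier and background flags, other values of the deposited files, are 0 or 1. Probe positions are those of build mm8 (NCBI36), per the file headers of the F1 and F2 arrays, and the M1 arrays carry the same probes. No sequence of this build was used here. The only reference table, of assembly GRCm38.p6, served for gene names and synonyms.

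The log2 of processed Cy5 over processed Cy3 was computed from the deposited intensity values, without loess. Control spots and spots marked as outliers in either channel were left out, spots of one probe were averaged, and each array was centred on the median of its autosomal probes. Of 42404 probes, 42235 had a position on a chromosome and 167 were unplaced, and 40386 were measured on all arrays. Outlier flags covered 2.32% and 2.68% of the spots of the M1 arrays and 0.265% to 0.490% of the others. Between 99.3% and 99.9% of the spots were well above background in both channels. Median raw signals were 1031 and 1185 (tumour) and 542 and 559 (liver) on the M1 arrays, and 458 to 536 and 280 to 302 on the others. The M1 arrays were on one slide and the F1 and F2 arrays on another.

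Each array was segmented by exact penalised least squares with a penalty of 3 times the noise variance times the logarithm of the number of probes for each breakpoint and at least 3 probes per segment. The noise came from differences of neighbouring probes. A segment was called gained or lost with at least 5 probes and a mean at least 0.2 from 0. A chromosome was called as a whole when called segments of one sign covered at least 80% of its probes. The same rule ran on 100 shuffles of the probe values of each array, after the mean of its segment was subtracted from each value. In simulations on the noise of the arrays, 48 segments per size and shift were tested. A shift of 0.25 was recovered in 97.9% of segments of 100 probes and in 39.6% of those of 30 probes. A shift of 0.5 was recovered in 68.8% of segments of 10 probes and 8.33% of those of 5 probes, and a shift of 1 in 95.8% of those of 5 probes.

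Values of single channels were compared between arrays within one dye, as medians of the difference over a chromosome, centred on the autosomal median. The exceptions are the Y probe and the X level over the autosomal median, which were also set side by side between the dyes of an array, where dye effects of single probes remain. The mouse, as labelled, was the unit of replication, with 2 tumours each. The altered percent, the sharing of calls and the correlation of 2-Mb bins were tested by exact permutation over the 15 ways to pair 6 tumours, and recurrence by 10000 random rotations of the calls of each mouse along the genome. Bins of at least 3 probes were tested with limma 3.58.1 (R 4.3.3), as the shift of 3 mouse means from 0 and as an F test between mice, with Benjamini-Hochberg adjustment at 0.05. In simulations with 200 of 1150 bins changed by 0.25, the first test found 100% and the F test found 69.5%, with 12 and 7 false calls, and at 0.5 both found 100%. The simulated bins had the spread between tumours of a mouse (SD 0.076) and no further spread between mice. For the first test all mice had the same shift, so its 100% need not hold for mice that differ. The limma p-values measure the spread between mice, or between the tumours of a mouse. Those of the pairings measure how tumours fall to mice, and those of rotations only placement along the genome in these tumours. A shared liver sample can make the tumours of a mouse more alike. Gene lists were tested against 10000 rotations of the gene positions with adjustment over 5 lists. The correlation of unchanged tumours set against a shared liver channel was simulated with independent probe noise.

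The genes and regions named were chosen by a rule fixed before the data were examined. It took the 10 called segments per tumour with the highest product of mean size and square root of the probe count, with all calls of whole chromosomes. It also took up to 25 list genes in called segments, up to 5 genes per called segment of at most 5 Mb, and Trp53, Cdkn2a, Myc, Met and Ctnnb1 in any case. Some genes the rule selects are not reported here. Of the segments it selects, some short losses of the F2 arrays are given only as counts. Segments under the threshold, the bins of the limma tests and the channel values were chosen after the values were seen. So were the difference of 1 log2 for single probes and the 0.05 for bins of opposite direction. Tumour numbers do not pair tumours of different mice, and the correlations of same-numbered deviations from the mouse means were 0.03, -0.06 and -0.16. Alternatives covered background correction (normexp with offset 50), loess, centring on the mode, probes well above background, the deposited table, outlier flags, the threshold, the probe minimum, the penalty, a hidden Markov model, 5-Mb bins, the slide, a replicate block, a random block for the mouse, and leaving out each tumour. The comparison restricted to the 3 arrays whose channels match on X was added after seeing the data. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9. Probe sequences and their GC content were not used here.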

Results

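Liver tumours were collected from 3 MF-1 mice, 1 labelled male (M1) and 2 labelled female (F1 and F2). The mice had received vector particles built from feline immunodeficiency virus, carrying a green fluorescent protein gene, through the yolk sac vein on day 16 of gestation. Genomic DNA of 2 tumours per mouse was compared with liver tissue around the tumours by array comparative genomic hybridisation, in which tumour DNA (Cy5) and liver DNA (Cy3) compete for the same probes. Each of the 6 arrays held 43020 spots, and 40386 probes (38908 on autosomes and 1478 on X, median spacing 22.8 kb) entered the analysis. The deviation of neighbouring probes, the noise of an array, ranged from 0.16 (M1 tumour 2) to 0.23 (F2 tumour 2) on the log2 scale. A tumour was hybridised once, so a value of a single tumour has no replicate, and errors of segment means are standard errors from probe noise. Precision is limited by the number of arrays.

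The first comparison asked which chromosomes each tumour had gained or lost relative to liver. On the array labelled M1 tumour 2, all of chromosome 1 was called lost, at -0.23 (SE 0.0052 over 89 bins of 2 Mb). On the array labelled F2 tumour 1, 97.7% of the chromosome 18 probes lay in gained segments, with a chromosome mean of 0.37 (SE 0.010, 42 bins). On the array labelled F2 tumour 2, 99.6% of the chromosome 2 probes lay in gained segments, with a chromosome mean of 0.24 (SE 0.0071, 87 bins). These 3 were the autosomes called as a whole in the 6 tumours, and each was called in 1 tumour. Chromosome 10 on the array labelled M1 tumour 2, with a mean of -0.17, stayed under the calling threshold of 0.2. Of 114 autosome means (19 autosomes in 6 tumours), 108 lay within 0.1 of 0. At a threshold of 0.1 the count of whole autosomes became 5, and at 0.3 it became 1.

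F1 tumour 1 carried partial changes of chromosomes 2 and 3. The distal part of chromosome 2, from 139109426 to 181785265 (mm8, 878 probes), was gained at 0.29 (SE 0.0059). On chromosome 3 the interval from 87535605 to 138091113 (1041 probes) was gained at 0.42 (SE 0.0054), and the interval from 141096312 to 159870361 (231 probes) was lost at -0.54 (SE 0.011). The gained interval of chromosome 3 held Nras, a RAS family GTPase, and Mcl1, an inhibitor of apoptosis. The rest of chromosome 2 on this array read -0.13, which is under the threshold. In F1 tumour 2 chromosome 2 had a mean of -0.18 (SE 0.0082, 87 bins), and 1 broad segment of it, from 97489718 to 118070920, was called lost at -0.21 (SE 0.0093, 286 probes).

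The low values of chromosome 2 in mouse F1 rest on its liver channel, while the distal gain of F1 tumour 1 lies in the tumour channel. Compared within one dye, the liver signal of chromosome 2 on both F1 arrays was higher than on the F2 arrays by 0.17 to 0.18 log2 and higher than on the M1 arrays by 0.19 to 0.20. The SD over 13 autosomes without broad changes was at most 0.025. The liver signals of M1 and F2 differed by at most 0.026 in size on chromosome 2. In the tumour channel, F1 tumour 2 lay 0.01 above M1 tumour 1 on chromosome 2 (SD 0.014). F1 tumour 1 lay 0.16 above it, F2 tumour 1 lay 0.14 above it and F2 tumour 2 lay 0.27 above it. Within F1 tumour 1, the tumour signal lay 0.06 above that of M1 tumour 1 on proximal chromosome 2 and 0.41 above it on the distal part. Chromosome 18 of F2 tumour 1 and the changed parts of chromosome 3 in F1 tumour 1 moved in the tumour channel, by 0.44, 0.38 and -0.55 against M1 tumour 1.

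**Figure D1:**
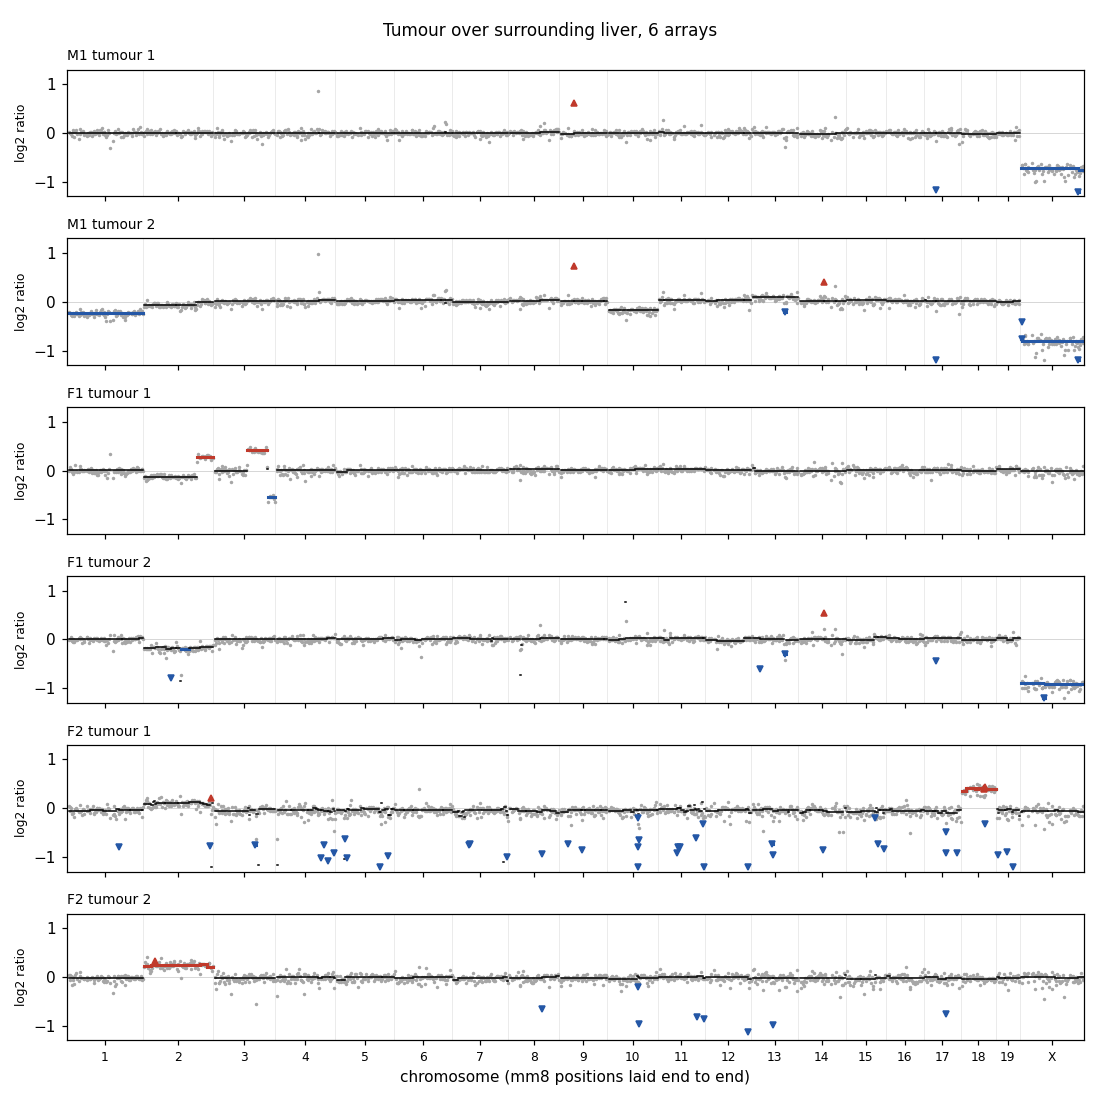
Log2 ratio of tumour over surrounding liver (vertical axis, values beyond 1.2 in size drawn at 1.2) along the genome (horizontal axis, mm8), 1 panel per array. Grey points are 2-Mb bin means, black lines are segments without a call, red and blue lines are gained and lost segments, and triangles mark called segments shorter than 5 Mb; the arrays labelled M1 tumour 1, M1 tumour 2 and F1 tumour 2 read low along all of X.

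**Figure D2:**
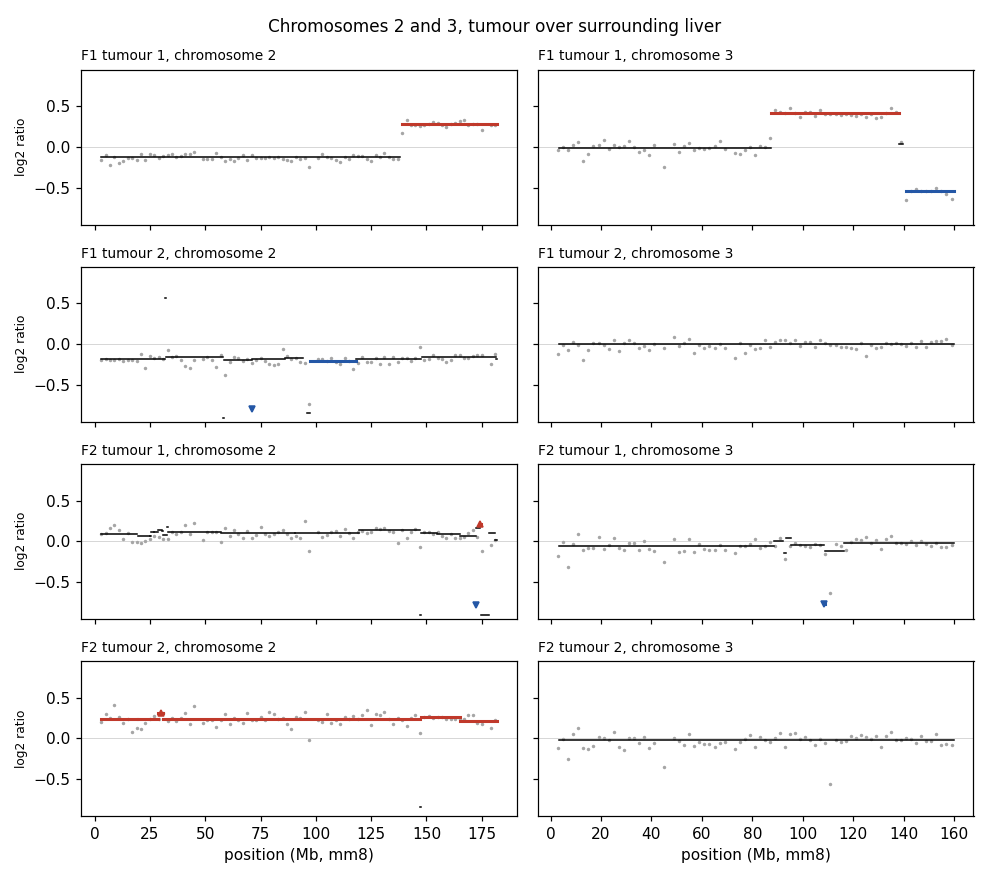
Log2 ratio of tumour over surrounding liver (vertical axis, values beyond 0.9 in size drawn at 0.9) along chromosomes 2 and 3 (horizontal axis, Mb, mm8) in the 4 tumours of mice F1 and F2. Points are 2-Mb bin means, and lines are segments, coloured red where gained and blue where lost (triangles where shorter than 5 Mb); the distal gain of chromosome 2 in F1 tumour 1 (0.29) lies within the gain of the whole chromosome in F2 tumour 2 (0.24).

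Both channels of an array come from the same mouse by the labels, so that X and Y serve as a check of the labels. All X probes lay in lost segments on the arrays labelled M1 tumour 1, M1 tumour 2 and F1 tumour 2, with chromosome means of -0.73 (SE 0.010), -0.80 (SE 0.012) and -0.91 (SE 0.012, 71 bins each). The X means of F1 tumour 1, F2 tumour 1 and F2 tumour 2 were -0.01, -0.07 and -0.01. Against the same dye of F1 tumour 1, X in the liver channel was at 0.01 and -0.0029 on the M1 arrays, at 0.01 on F1 tumour 2, and at -0.88 and -0.89 on the F2 arrays. In the tumour channel it was at -0.70 and -0.78 on the M1 arrays, at -0.86 on F1 tumour 2, and at -0.84 and -0.83 on the F2 arrays. The 1 probe on an unplaced Y contig gave tumour signals of 863, 334 and 663 on the 3 arrays with low X, against liver signals of 180, 165 and 58.5. On the F2 arrays its signals were 640 and 418 in the tumour and 703 and 735 in the liver channel, and on F1 tumour 1 they were 31.3 and 26.9. The liver channel of the arrays labelled M1 thus read like the X level of the female F1 liver, against the label male. The tumour channel of F1 tumour 2 and both channels of the F2 arrays read at the low X level with Y signal, against the label female. The names used here are those of the labels throughout.

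**Figure D3:**
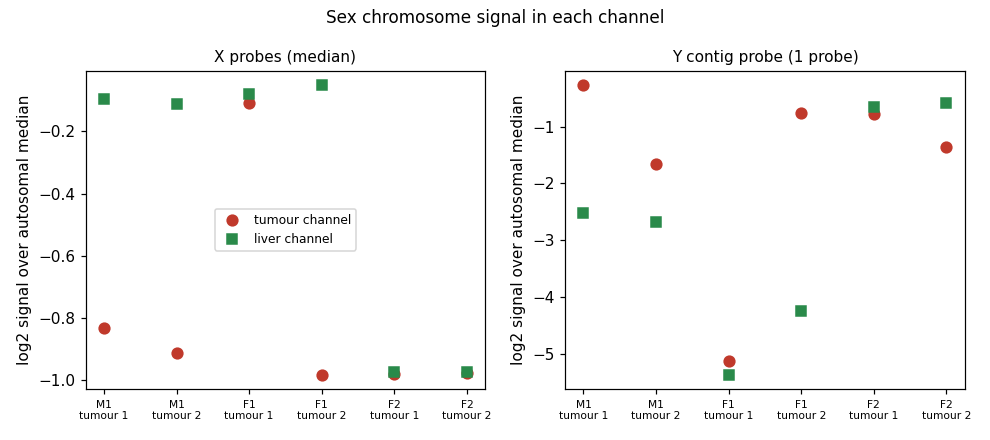
Signal of the X probes (left, median) and of the single Y contig probe (right), each as log2 over the autosomal median of the same channel (vertical axes), for the 6 arrays by their labels. Circles are the tumour channel and squares the liver channel; the 2 channels lie apart on X on the arrays labelled M1 tumour 1, M1 tumour 2 and F1 tumour 2, and together on the other arrays.

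The altered share of the autosomes was small in all tumours. It was 0.0334% of the probes in M1 tumour 1 and 6.84% in M1 tumour 2, 5.53% in F1 tumour 1 and 0.871% in F1 tumour 2, and 3.76% in F2 tumour 1 and 8.91% in F2 tumour 2. In F1 tumour 2 most of these probes belong to the segment of 286 probes on chromosome 2, which rests on the liver channel. Per mouse this gave 3.44% ± 4.81 (SD, n = 2) for M1, 3.20% ± 3.29 (SD, n = 2) for F1 and 6.33% ± 3.64 (SD, n = 2) for F2. The means differed by less than the spread between the tumours of a mouse (two-sided exact permutation test over the 15 pairings of 6 tumours, p = 0.733; the smallest p these allow is 0.0667). With a threshold of 0.1 the means became 5.93% in M1, 10.4% in F1 and 9.70% in F2, and with 0.3 they became 0.0475% in M1, 1.70% in F1 and 1.96% in F2.

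In all, 80 autosomal segments were called. There were 2 in M1 tumour 1, 5 in M1 tumour 2, 3 in F1 tumour 1, 6 in F1 tumour 2, 50 in F2 tumour 1 and 14 in F2 tumour 2. Shuffled probe values gave at most 1 call in the M1 tumours and F1 tumour 1 and at most 3 in F1 tumour 2 over 100 shuffles. They gave at most 22 in F2 tumour 1 and at most 5 in F2 tumour 2. Segment means were subtracted before shuffling, which also removes runs of outlying probes, so these counts are not a full measure of false calls. The count of 80 called segments moved with the calling rules, from 30 to 355 over the alternatives, and it was 30 without F2 tumour 1.

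Low values were called at Glo1, which encodes glyoxalase I, on the 3 arrays whose channels differ on X and Y, so that neither this nor the other short calls of these arrays can be taken as changes of the tumours. The interval on chromosome 17 from 30304379 to 30650272 (8 probes at AK002941, Glo1, Dnahc8 and Glp1r, the receptor of glucagon-like peptide 1) was lost at -1.16 (SE 0.07) in M1 tumour 1 and at -1.36 (SE 0.06) in M1 tumour 2, and it read -0.49 in F1 tumour 2, inside a loss from 30104345 to 30650272 that also held Btbd9. In the other tumours its mean lay between -0.21 and -0.05. A gain on chromosome 9 from 37858715 to 37877261 (5 probes, no gene named) was called in both M1 tumours at 0.61 and 0.73. On chromosome 14 the interval from 66325799 to 66786755 (11 probes at Ebf2, Cdca2 and unnamed transcripts) was called gained in M1 tumour 2 (0.40) and F1 tumour 2 (0.54), and it read 0.33 in M1 tumour 1, 0.12 in F1 tumour 1, -0.26 in F2 tumour 1 and -0.18 in F2 tumour 2. On chromosome 13 the interval from 85619033 to 90044529 (18 probes at Ccnh, Rasa1, Cox7c and Edil3) was called lost in M1 tumour 2 (-0.21) and within a longer loss in F1 tumour 2 (-0.30), but it was below 0 on all 6 arrays (-0.30 in M1 tumour 1, -0.16 in F1 tumour 1, -0.15 in F2 tumour 1 and -0.22 in F2 tumour 2). F1 tumour 2 alone lost 7 probes at Slc25a12, Hat1 and Metapl1 on chromosome 2, from 71108286 to 71277372, at -0.79. It also lost 5 probes at Slc17a1 and Slc17a4 on chromosome 13, from 23902797 to 23939238, at -0.61. The probes inside these losses also spread more than noise, with a median SD of 1.64 times the noise in M1 tumour 1 (the loss at Glo1), 2.59 times in M1 tumour 2 (2 losses) and 3.92 times in F1 tumour 2 (4 losses).

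The arrays labelled F2 carried most short losses, 41 in F2 tumour 1 and 8 in F2 tumour 2. Those of F2 tumour 1 with the highest scores lay at Mbd3 and Tcfe2a on chromosome 10 (79744700 to 79855169, -1.73), at Kctd10, Ube3b and Mmab on chromosome 5 (114626293 to 114698230, -1.85), at Got1, Nkx2-3 and Slc25a28 on chromosome 19 (43558137 to 43720313, -1.55), and at 2010107E04Rik and BC089617 on chromosome 12 (112392662 to 112624364, -1.55). The last of these was also called in F2 tumour 2, at -1.13. In F2 tumour 2 the highest-scoring short loss lay at Dbn1, Pdlim7, Dok3 and Ddx41 on chromosome 13 (55491890 to 55549002, -0.98), next to -0.96 in the called segment of F2 tumour 1 from 55491890 to 55545226. Other short losses held Mast1 and Hook2 on chromosome 8 (87808049 to 87901368, -0.95 and -0.66), Ncln, Gna15 and Gna11 on chromosome 10 (80896536 to 80934302, -0.97 in F2 tumour 2) and Shh on chromosome 5 (28724771 to 28797877, -1.03 in F2 tumour 1). The probes inside these segments did not move as 1 block. Their median SD was 5.65 times the noise of the array in F2 tumour 1 and 4.77 times in F2 tumour 2.

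The second comparison asked whether the tumours of one mouse shared changes. Tumours of the same mouse shared calls of the same direction at 0.0720% of the autosomal probes on average, and tumours of different mice at 0.20% (one-sided exact permutation test over 15 pairings, p = 0.333). The pair with the highest share, 2.24%, came from different mice, F1 tumour 1 and F2 tumour 2, through distal chromosome 2. Within mice, both M1 arrays shared the low call at Glo1 and the high call on chromosome 9. These calls need not be changes of the tumours, because the channels of the M1 arrays differ on X and Y. The F1 tumours shared no autosomal probe. Their tumour channels differ on X and Y, so that they do not read as DNA of the same mouse. The F2 tumours shared 64 lost and 7 gained probes. All autosomal losses called on the F2 arrays were short losses, whose probes did not move as 1 block. The 64 lost probes thus need not be changes of the tumours. The sign of the difference in sharing turned with the threshold, and at 0.1 the tumours of one mouse shared 3.38% (exact permutation p = 0.0667). At 0.1, 73.9% of the chromosome 2 probes of F1 tumour 1 and 99.3% of those of F1 tumour 2 count as lost. These are set against the F1 liver with the higher chromosome 2 signal. The F2 pair enters too, with 40.5% of the chromosome 2 probes of F2 tumour 1 and 99.6% of those of F2 tumour 2 counted as gained. That gain lies in the tumour channel.

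Profiles of 2-Mb bins were on average more alike within mice, though not in every pair. Across bins, which are not independent replicates, the correlation was 0.49 for the M1 tumours, 0.23 for the F1 tumours and 0.51 for the F2 tumours. M1 tumour 1 and F2 tumour 2, from different mice, correlated at 0.25, above the F1 pair. The mean was 0.41 within mice and 0.04 between mice, a difference of 0.36 (exact permutation p = 0.0667, the smallest that 15 pairings can give). The tumour channels of the F1 arrays differ on X and Y, so that they do not read as DNA of one mouse. Over the 3 arrays whose channels match on X the difference was 0.48 (exact permutation p = 0.333, the smallest that 3 arrays can give). In simulations of independent probe noise, unchanged tumours set against one shared liver channel gave a correlation of 0.50. This value follows from equal noise in the channels. The covariance was 0.0036 within mice and 0.00029 between mice, and 0.0010 in the simulation. The simulation held no broad liver differences, such as that of F1 on chromosome 2. It cannot show how much likeness a shared liver gives. Whether the tumours of a mouse were set against one liver extract is not known, and if so, part of the likeness may come from the liver channel. F1 tumour 2 and F2 tumour 2 correlated at -0.35 over bins. Over autosomal probes the correlation was 0.75 for the M1 tumours, 0.33 for the F1 tumours and 0.72 for the F2 tumours. F1 tumour 2 correlated there at 0.18 and 0.25 with the M1 tumours, and F1 tumour 1 at 0.34 and 0.32, close to the 0.33 within F1. All M1 arrays were on one slide and all others on a second one, so slide and mouse M1 cannot be told apart.

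The third comparison asked which changes recurred in separate mice. Calls of the same direction in at least 2 mice covered 2.36% of the autosomal probes (917 probes). The test did not set this share apart from random placement of the calls (10000 rotations, one-sided permutation p = 0.116). Most of the recurrent probes lay on distal chromosome 2, gained in F1 tumour 1 and F2 tumour 2. The gained intervals ran from 139109426 to 147056104 (0.26 and 0.26), from 147402167 to 165096566 (0.29 and 0.26) and from 165233648 to 181785265 (0.28 and 0.21). F1 tumour 2 read -0.18, -0.15 and -0.15 there, against its liver with the higher chromosome 2 signal. Without F1 tumour 1 the recurrent share was 0.116%, and without F2 tumour 2 it was 0.134%.

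No 2-Mb bin was shifted from 0 across the 3 mouse means (limma with Benjamini-Hochberg adjustment, 0 of 1150 bins, 86 at an unadjusted p under 0.05). The bin with the smallest p, on chromosome 1 from 118000001 to 120000000, had a mean of -0.23 and was below 0 in 3 of 3 mice (limma adjusted p = 0.336). Between the mice, 1 bin differed (limma F test, 223 at an unadjusted p under 0.05). It lay on chromosome 4 from 110000001 to 112000000, with means of 0.92 in M1, 0.01 in F1 and -0.07 in F2 (limma adjusted p = 0.0146). No bin was left with the tumour number as a block (adjusted p = 0.0886), and M1 was also alone on its slide. The channels of both M1 arrays differ on X and Y, so that the bin need not mark a change of the tumours. The count was 30 without F1 tumour 2, 60 without F2 tumour 2 and 0 without any one of the other 4 tumours, and it was 0 with normexp and with bright probes only. As a whole, chromosome 2 averaged -0.02 in M1, -0.10 in F1 and 0.16 in F2 (limma F test, adjusted p = 0.271 over 19 autosomes).

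Genes of 5 lists chosen before the data were examined were then placed on the segments, 111 of 124 being measured. Of these, 25 lay in a segment called in at least 1 tumour. No list differed from random rotations of its positions along the genome. Of 29 oncogenes of hepatocellular carcinoma, 5 were gained and 2 lost in at least 1 tumour (mean segment value -0.016, permutation p = 0.233, adjusted p = 0.403). Without F2 tumour 1, where short low segments held Ccnd1 and Fgf15 (-1.18 each, uncalled), the mean was 0.0082. On distal chromosome 2, Aurka, a mitotic kinase, and E2f1, a cell cycle transcription factor, lay in gained segments of F1 tumour 1 (0.29) and F2 tumour 2 (0.21 and 0.26). The own 2 probes of Aurka averaged 0.21 in F1 tumour 1 but -0.08 in F2 tumour 2. Nfe2l2, a regulator of the oxidative stress response, lay in a gained segment of F2 tumour 2 (0.24). Nras and Mcl1 were gained in F1 tumour 1 (0.42). Mdm4, an inhibitor of p53, lay on the lost chromosome 1 of the array labelled M1 tumour 2 (-0.23). Erbb2, a receptor tyrosine kinase, lay in a short lost segment of F2 tumour 1 (-0.60), but its own 2 probes averaged 0.01.

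Of 32 tumour suppressors, 4 were gained and 2 lost in at least 1 tumour (permutation p = 0.321, adjusted p = 0.403). Apc, a negative regulator of Wnt signalling, and Smad4, a mediator of TGF-beta signalling, lay on the gained chromosome 18 of F2 tumour 1 (0.41 and 0.39). Stk4, a kinase of the Hippo pathway, was gained in F1 tumour 1 (0.29) and F2 tumour 2 (0.26). Tsc1, an inhibitor of mTOR signalling, was gained in F2 tumour 2 (0.24). Stk11 lay in one of the short lost segments of F2 tumour 2 (-0.21), whose probes did not move together, and its own probe read -0.12. The other member counted as lost, Rps6ka3, followed X on the arrays whose channels differ, which is not taken as a loss by the tumours, and read -0.75, -0.81 and -0.91 on the arrays labelled M1 tumour 1, M1 tumour 2 and F1 tumour 2.

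Of 22 genes of hepatocyte function, 5 were gained and 2 lost in at least 1 tumour. The mean segment value of the 21 autosomal ones, 0.018, lay above the mean of -0.0061 over the rotations (permutation p = 0.0337, adjusted p = 0.168), which did not pass the adjustment. X genes were left out of the list tests. The highest value in this mean, 0.82 for Foxa2 in F1 tumour 2, came from an uncalled segment of 3 probes, and its own probe there read 0.02. The gained members were Foxa2 and Hnf4a, transcription factors of hepatocytes, and Pck1, a gluconeogenic enzyme, in F1 tumour 1 (0.29) and F2 tumour 2 (0.26, 0.26 and 0.21), although the own probe of Pck1 read -0.0015 in F1 tumour 1. Ass1, an enzyme of the urea cycle, was gained in F2 tumour 2 (0.24), and Ttr, which encodes transthyretin, in F2 tumour 1 (0.41). Glul, the glutamine synthetase gene, was lost with chromosome 1 in M1 tumour 2 (-0.23), and Otc, another gene of the urea cycle, is counted as lost only because it followed X (-0.72, -0.80 and -0.90 on the 3 arrays with low X). Of 25 genes of DNA repair and chromosome segregation, 3 were gained and 2 lost (permutation p = 0.898, adjusted p = 0.898). Bub1 and Bub1b, of the spindle checkpoint, lay in gained segments of F2 tumour 2 (0.24). Parp1 and Xrcc5 lay on the lost chromosome 1 of M1 tumour 2 (-0.23). All 3 measured genes of the Dlk1-Dio3 region were uncalled in the 6 tumours (permutation p = 0.322, adjusted p = 0.403).

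Myc, Met, Ctnnb1, Trp53 and Cdkn2a were uncalled in the 6 tumours, with segment means at most 0.07 from 0 in size. The segment means of Trp53 ranged from -0.07 to 0.03 and those of Myc from -0.05 to 0.03. The single probe of Myc itself read -0.85 in F2 tumour 1 and between -0.16 and 0.16 in the other tumours. The antigen receptor loci, which lose copies in lymphocytes, were measured by few probes. Igk was below 0 in 6 of 6 tumours and averaged between -0.05 in F1 tumour 1 and -0.23 in F1 tumour 2 over 8 probes (SE 0.06 for both). Igh averaged between -0.21 in F2 tumour 2 and 0.0011 in F1 tumour 2 over 5 probes, and Tcrb between -0.09 and 0.05 over 5 probes.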

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

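The tests in this part were chosen only after the results were seen. The Y contig probe, outside the measurement of autosomes, was higher in tumour than in liver by more than 3 times the noise of the array on 3 arrays, at 2.24 log2 in M1 tumour 1, 0.99 in M1 tumour 2 and 3.48 in F1 tumour 2. These are the arrays on which X was lower in the tumour channel. A loss of X by tumour cells leaves Y unchanged, so these ratios argue against it as the cause, the lowest, 0.99, only weakly. On F2 tumour 2, whose channels match on X, the same probe read -0.80. That is also more than 3 times the noise of its array in size, so this probe can differ without X. Background correction and normalisation are argued against by the X mean nearest 0 over these arrays and all ratio alternatives, -0.72. The values are consistent with tumour and liver channels that hold DNA of different animals, which needs a Y signal in the tumour on all 3 arrays (lowest 0.99), but it rests on 1 Y probe beside X and was read from the same arrays. Single autosomal probes are less clear, with 170 probes at least 1 log2 apart between the tumour channels of F1, 15 between those of M1 and 515 between those of F2. Liver channels of one mouse had 5 (M1), 45 (F1) and 74 (F2) such probes, and livers of F1 and F2 had 183 to 230. Tumour channels of F1 and F2 had 767 to 1189, most of them lower on the F2 arrays, so the 170 lies well under that level. A wrongly recorded sex leaves the channels of an array alike and so does not account for these 3 arrays. Exchange and mixing of samples were not told apart, and how the channels came to differ stays open.

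On chromosome 2, 49 of 87 bins of 2 Mb were lower than liver in both F1 tumours and higher than liver in both F2 tumours, each by at least 0.05. The difference of these bins was not tested as such, and the limma F test of the whole chromosome over the 3 mice gave an adjusted p of 0.271. A loss of chromosome 2 in F1 tumour 2 is argued against by its tumour channel, which lay 0.011 above that of M1 tumour 1. Centring moves all autosomes of an array by the same amount, so it cannot set chromosome 2 apart from the others. The farthest of the other autosomes of F1 tumour 2 lay 0.027 from 0. That value is no separate test, since the array was centred on its autosomal median. More chromosome 2 in the F1 liver DNA could account for the F1 side, since the lowest of the 8 differences to liver channels of other mice was 0.17, while the F2 side lies in the tumour channel (0.14 and 0.27 above M1 tumour 1). Cells of the 2 tumours on the F1 arrays are argued against as the source of the liver signal, since a mixture cannot exceed its parts. On proximal chromosome 2 their tumour channels lay 0.06 and 0.02 above M1 tumour 1, under the 0.17 of the liver over the whole chromosome. Whether the F1 liver sample held cells of another tumour or the liver itself had changed was not tested. A difference between the mice stays open.

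The short losses of the F2 arrays were weighed as a further pattern. For scattered noise, the shuffles gave at most 22 calls against 41 short losses in F2 tumour 1. In F2 tumour 2 they gave at most 5 against 8. Segment means were subtracted before shuffling, which pulls the low probes of these losses towards 0. The shuffles therefore cannot argue against scattered low probes. Copy losses in all tumour cells shift the probes of a segment together, and the median SD inside the losses, 4.77 times the noise on the array with the lower value, argues against them. Lower tumour signal where probes are dense, as they are near genes, may contribute, but its tests went different ways. The bins of the losses held a median of 69 and 80 probes, against 45 and 45.5 for random probes (permutation p = 0.00030 and 0.0070 with 10000 draws). Over all bins, the Spearman correlation of bin value and probe density was -0.027 in F2 tumour 1 and 0.24 in F2 tumour 2, against 0.11, 0.22, 0.29 and 0.23 on the M1 and F1 arrays, so that only F2 tumour 1 stood apart. On single probes the same arrays had 942 and 439 probes at least 1 log2 lower in tumour and 30 and 90 higher. GC content and DNA quality were not tested, and the explanation stays open.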

How the results depend on the processing

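Among the comparisons of a result of the report with an alternative, 207 stayed the same, 23 moved and 11 reversed. Among those of single chromosome and segment values, 71 stayed the same and 31 moved. A test counted as the same when its sign held and its p stayed on 1 side of 0.05. The pairings cannot give p under 0.0667, so their tests could only stay or reverse. An altered mean counted as the same within the SD between the tumours of a mouse. By this rule M1 stayed the same from 0.0334% to 6.84%. Part of the 207 is thus built into the labels. X on the F2 arrays read -0.17 and -0.18 with normexp. Alternatives run on whole-autosome counts, whole-X counts, gene lists and the 3 arrays whose channels match on X were chosen after seeing the data. The cause was not tested unless stated. A threshold of 0.1 gave an altered mean of 10.4% in F1, 129 segments, 5 whole autosomes and a within-mouse sharing of 3.38% (exact permutation p = 0.0667), above that between mice. The low values of chromosome 2 in F1, which rest on the liver channel, enter these results. On the F1 arrays 73.9% and 99.3% of the chromosome 2 probes are counted as lost. The F2 arrays enter the sharing too, with 40.5% and 99.6% of the chromosome 2 probes counted as gained. A threshold of 0.3 gave altered means of 0.0475% in M1 and 1.96% in F2, 1 whole autosome and a sharing of 0.0411%, again above that between mice. Segment counts were 30 with normexp, 31 with penalty factor 6, 32 with at least 10 probes, 355 with at least 3 probes and 258 with the hidden Markov model, which also turned the sharing (0.512%). Without F1 tumour 1 the sharing was 0.108% and turned too. Bins differing between mice fell from 1 to 0 with normexp, bright probes, 5-Mb bins, the female slide and the 3 arrays whose channels match on X. With the tumour number as a replicate block the count was 0, and the numbers do not pair the tumours. The oncogene list turned sign against the rotations with normexp (-0.0099), penalty factor 6 (-0.0012) and without F2 tumour 1 (0.0082). The DNA repair list turned with normexp (-0.019), penalty factor 6 (-0.010), without F2 tumour 1 (-0.0017) and without F2 tumour 2 (-0.0093). No list passed its adjusted test in any alternative (lowest adjusted p 0.126).

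Leaving out 1 tumour in turn, the altered mean ranged from 0.0334% to 6.84% in M1, 0.871% to 5.53% in F1 and 3.76% to 8.91% in F2. Segments ranged from 30 to 78, sharing from 0.0167% to 0.108%, recurrence from 0.116% to 2.36% and the correlation difference from 0.28 to 0.47. Bins shifted from 0 stayed at 0, and bins differing between mice ranged from 0 to 60, where the lone tumour of a mouse is assumed to vary like the others. Mean values of the lists ranged from -0.030 to 0.0082 (oncogenes), -0.0021 to 0.0048 (tumour suppressors), 0.012 to 0.023 (hepatocyte function), -0.0093 to -0.0017 (DNA repair) and 0.0043 to 0.016 (Dlk1-Dio3). X was called lost on 3 arrays under all 13 alternatives tried for it. At least 99.3% of spots were well above background, and 83 segments were called on such probes alone.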

Other observations

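Some values belong to no comparison of the report. Chromosome 13 on the array labelled M1 tumour 2 had a mean of 0.09 (SE 0.0077 over 59 bins), and on F2 tumour 1 chromosome 2 had a mean of 0.08 (SE 0.0072 over 87 bins), both under the calling threshold. The tumour channel of M1 tumour 2 lay below that of M1 tumour 1 on chromosomes 1 (-0.24) and 10 (-0.17), with an SD of 0.0071 over 13 other autosomes. M1 tumour 1 and M1 tumour 2 had 81 and 87 autosomal probes at least 1 log2 from their neighbourhood, of which 65 were shared with the same sign and 0 with the opposite sign. F2 tumour 1 and F2 tumour 2 had 972 and 529 such probes and shared 440 with the same sign. F1 tumour 1 and F1 tumour 2 had 58 and 112 and shared 1 with the same sign and 3 with the opposite sign. F1 tumour 2 shared 15 with M1 tumour 1 and 19 with M1 tumour 2 with the same sign, and 6 and 7 with the opposite sign. Chosen after the values were seen and outside the rule for named genes, on F2 tumour 1 the 2 probes of Igf2 averaged -1.49 and the single probe of Ccnd1 read -2.31, and on F2 tumour 2 they read -1.19 and -1.85, without a called segment.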
